A study of Lotus japonicus with 4 samples.

How the data were processed

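Small RNAs of roots of wild-type Lotus japonicus, a model legume, were measured in 4 libraries. Per the labels' protocols, seedlings stood on medium with 1 mM KNO3 and received 100 µl per root of a suspension of Mesorhizobium loti at an optical density of 0.01, or the same volume of sterile medium (mock), at day 7 after germination. M. loti is the nitrogen-fixing bacterium that forms root nodules on this plant, and the strain used carried the red fluorescent marker DsRed. Roots were frozen at day 10, which the labels call 3 dpi, and each library came from 10 to 15 root systems. Per the labels' protocols, small RNAs of about 18 to 28 nt were cut from a gel from 10 µg of total RNA, ligated to a 3′ and then a 5′ RNA adapter, copied and amplified over 12 PCR cycles and sequenced for 36 cycles.

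The authors' deposited table gives raw read counts per distinct small RNA sequence in each library, per the file headers. The values showed whole numbers, lengths of 19 to 24 nt and a sum over the 4 libraries of at least 11 in each row. Sequences below that sum are not used here, so a column total is the depth of the table and not of the library. A few lines were emptied before the table was analysed here, 8 sequences that held letters other than the 4 bases were left out, and a last line with a column total was not treated as a sequence. The submitters' processing notes name Bowtie, with no version, and R 2.13.0, with no role for either. The file headers name hits to the L. japonicus genome release 2.5, miRBase release 19 mature miRNAs, a Fabaceae repeat set, the M. loti genome, and miRNA and ta-siRNA predictions. The mismatches allowed in these hits are not given in the sources used here. The authors' scaled values, a signal deposited beside the counts, equalled the count (0 set to 1) multiplied by the smallest column total over the library's own, with factors of 0.954, 0.338, 1 and 0.364 for mock A, mock B, inoculated A and inoculated B. The deposited score per sequence was not used, since its formula is not given in the sources used here.

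From the counts, the inoculated libraries (n = 2) were compared with the mock libraries (n = 2) by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM factors, after a filter on low counts (filterByExpr, minimum count 10). Benjamini-Hochberg adjusted p under 0.05 was the threshold, and the standard error of a log2 fold change was its size divided by the square root of the F statistic. Reads were assigned to 34 miRNA families from 48 mature sequences fixed before the data were examined, with a shift of at most 2 nt, at least 18 aligned bases and at most 2 mismatches. Family sums were tested in the same way with the library sizes and TMM factors of the whole table. Reads with a miRBase hit to a family that paired with its mature sequence (at least 16 aligned bases, at most 6 mismatches, a shift of at most 4 nt) were summed as the opposite arm, a step chosen after the data were seen. The 8 lists of families, also fixed before, were tested on log2 CPM with fry and camera (limma 3.58.1). Shares of counts by length were compared by an exact two-sided permutation test, whose smallest p with 2 against 2 libraries is 0.333. Levels are reads per 1e+06 counts of the library (RPM) as mean ± SD over 2 libraries. The p-values measure the spread between these samples. The end of the 5′ adapter differed between the groups, as given in the Results, so the p-values cannot tell inoculation from adapter end. The labels call A and B biological replicates of 10 to 15 root systems, and do not say whether equal letters mark plants grown or handled together.

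The rule for named items was also fixed before. It took the 10 sequences with the largest rise and the 10 with the largest fall among those past the threshold, with one direction in all 4 pairs of libraries and a mean of at least 20 counts. It also took up to 4 miR172 sequences, the miR172 family, each family past the threshold and the 10 families with the most counts. Other sequences are named as chosen after their values were seen. Sequences with no hit to the plant genome are not printed unless they hold the adapter bases. A ratio against a group without counts was computed against a floor of 3 counts over the group, and 95% intervals of ratios are exact (Clopper-Pearson). Floors and intervals cover counting error only, since PCR copies cannot be told from separate molecules.

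Alternatives were DESeq2 1.42.0, its size factors, library totals alone, other filters on counts and length, the replicate letter as a block, each library left out, other assignments of reads to families, library sizes from family reads, and limma on the log2 of the authors' scaled values with a pseudocount of 1 or 5. Tests without adapter reads, without ribosomal sequences or without certain motifs were added after seeing the data. A ridge model (scikit-learn 1.9.0, 1664 features of bases, 4-mers and 5-mers, 5 folds) related log2 fold change to sequence and was also added after seeing the data. Its folds were split by family, else by the first listed genome position, or by part of the sequence where there was no hit. Similar sequences could thus lie in different folds. The tests were tried on simulated counts with a dispersion of 0.1. Of 200 sequences changed among 89736 by 2-, 4- and 16-fold, the test recovered 0%, 14.5% and 96%. Of families changed by 2-, 4- and 16-fold among 27, it recovered 11.2%, 86.2% and 100%.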

Results

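Small RNA libraries of L. japonicus roots at 3 days after inoculation with M. loti were set beside libraries of mock-treated roots, with 2 libraries in each group. The series is about miR172, and the comparison asks which small RNAs differ in roots at an early stage of the symbiosis. The table held 378295 distinct sequences of 19 to 24 nt. Total counts were 2771373 in mock A, 7831713 in mock B, 2644713 in inoculated A and 7258305 in inoculated B. Sequences with a hit to the plant genome made up 86.9%, 88.7%, 85.1% and 86.4% of these counts in the same order. Ribosomal repeats took 18.7% and 18.8% of counts in the A libraries and 24.7% and 25.1% in the B libraries. The groups also differed in the end of the 5′ adapter, as given below, so the design does not separate inoculation from adapter end.

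The miR172 family, whose known targets are AP2-type transcription factors of flowering and development, was 220-fold higher in inoculated than in mock roots (log2 fold change 7.78, SE 0.67, adjusted p = 9.3e-15, edgeR quasi-likelihood test). Its level was 7.07 ± 0.299 RPM in mock roots and 1431 ± 282 RPM in inoculated roots (SD, n = 2 each). Most of these reads were 1 sequence, AGAATCTTGATGATGCTGCAG, with 2 and 0 counts in mock A and B and 4100 and 8261 in inoculated A and B. The ratio of its pooled shares was 6617, with a lower 95% bound of 1831. Its log2 fold change was 12.50 (SE 1.37), and ranged from 11.07 to 15.91 with 1 library left out. The sequence AGAATCTTGATGATGCTGCAT, with another last base, was already present in mock roots at 6.03 ± 0.868 RPM and reached 39.8 ± 4.46 RPM in inoculated roots (log2 fold change 2.86, SE 0.52, adjusted p = 0.0060, and 0.069 without mock A). AGAATCTTGATGATGCTGCAGT, which is 1 nt longer, had 1 count in mock roots and 41 and 104 in the inoculated libraries (log2 fold change 6.99, SE 0.94, adjusted p = 0.0052), a ratio of pooled shares of 155 with a lower 95% bound of 27.4, and its log2 fold change ranged from 5.52 to 9.44 with 1 library left out. AGACTCTTGATGATGCTGCAG had no count in mock roots and 3 and 70 in inoculated A and B, 26.1-fold higher against the floor, with a lower 95% bound of 20.7. Most of its counts came from inoculated B, and it was below the filter on low counts.

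In genome release 2.5 the authors' table lists the sequence ending in CAG at chromosome 3, positions 41950194, 41190790 and 22727682, and at position 289070 of the part it calls chromosome 0. The sequence ending in CAT is listed at 3 of these positions too and at 2 of its own, the first at chromosome 3, position 41190719. Hits shared by different sequences must hold mismatches, so they do not tell which locus a read came from. The table does not state whether its positions count from 0 or 1, and annotated genes at these positions were not analysed here. The miR172 family stayed past the threshold in each alternative, and without the sequence ending in CAG its log2 fold change was 3.83.

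Among 27 families detected, 12 were higher in inoculated roots and none was lower at an adjusted p under 0.05, and 13 had an unadjusted p under 0.05 (DESeq2 called 13 higher and none lower, with miR390 at 1.41 and adjusted p = 0.036 besides). After miR172, the largest rises were in miR170/miR171, which is known to target GRAS-domain regulators, at 11.4-fold (log2 fold change 3.51, SE 0.56), and in miR398, known to target copper/zinc superoxide dismutases, at 10.5-fold (3.39, SE 0.53). The miR160 family, known to target auxin response factors, rose 10.0-fold from 52.1 ± 17.1 to 467 ± 247 RPM. NAC-targeting miR164 rose 8.47-fold from 95.8 ± 15.0 to 740 ± 402 RPM. The miR156/miR157 family, known to target SPL factors of phase change, rose 6.77-fold from 520 ± 15.6 to 3192 ± 979 RPM. The miR482 family, known to target NB-LRR disease resistance genes, rose 6.68-fold from 163 ± 4.34 to 965 ± 211 RPM. The other rises were 4.47-fold for miR394, 3.48-fold for miR167, 3.38-fold for miR408, 3.26-fold for miR168 and 2.65-fold for miR396, with adjusted p between 0.0028 and 0.023. Each of the 12 was higher in both inoculated libraries than in both mock libraries. This does not mark the called families, since it also held for miR390, miR162, miR1510, tasiR-ARF, miR2111 and miR165/miR166, which were not called. Others not called, such as miR397, miR169, miR159 and miR1511, were lower in both inoculated libraries.

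**Figure D1:**
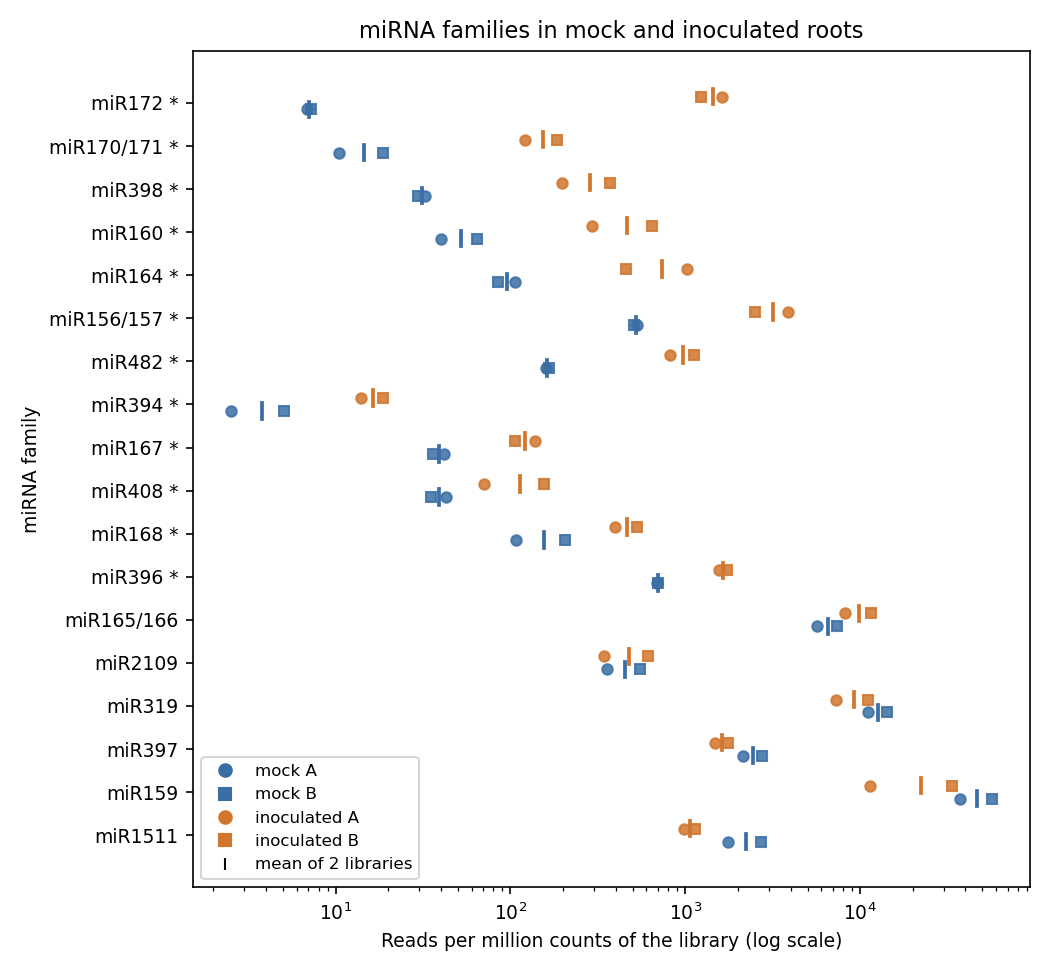
Level of each named miRNA family in each library, in RPM on a log axis. Circles are A libraries, squares are B libraries, blue is mock, orange is inoculated, and a vertical bar marks the mean of 2 libraries. Families with an asterisk passed the threshold, and miR172 had the widest gap, at 7.07 RPM in mock and 1431 RPM in inoculated roots.

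The 5 most abundant families did not pass the threshold in the main fit. With the replicate letter as a block in the same test, miR159 (-1.07, adjusted p = 0.0092) and miR1511 (-0.88, adjusted p = 0.0035) passed as lower. With that block miR165/miR166 (0.75, adjusted p = 0.022) passed as higher. The miR159 family, known to target MYB factors, had 46847 ± 13669 RPM in mock and 22396 ± 15638 RPM in inoculated roots (log2 fold change -0.88, SE 0.90, adjusted p = 0.41). For miR319, known to target TCP factors, the log2 fold change was -0.29 (SE 0.72, adjusted p = 0.70). For miR165/miR166, known to target HD-ZIP factors, it was 0.76 (SE 0.69, adjusted p = 0.38). It was -0.10 with library sizes from family reads, and 1.79 with only exact matches to a mature sequence, where it passed (adjusted p = 0.019). Laccase-targeting miR397 was at -0.44 (SE 0.56, adjusted p = 0.49) and miR1511 at -0.93 (SE 0.54, adjusted p = 0.16), which passed with library totals alone (-1.07, adjusted p = 0.024) and with at least 50 counts in 2 libraries (-0.88, adjusted p = 0.045). For miR2109 the value was 0.24 (SE 0.48, adjusted p = 0.67), and it was -0.63 with library sizes from family reads.

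The number of families called moved with the libraries and the scaling. Leaving out mock A left 5 families higher and leaving out mock B left 6, and none was lower in either case. In each case with 1 library left out, miR172, miR170/miR171, miR398, miR160 and miR164 still passed, and miR394 and miR396 did not. The call of miR482 ended without mock A, those of miR156/miR157 and miR167 without either mock library, that of miR408 also without inoculated B and that of miR168 also without inoculated A. Over these cases the log2 fold change ranged from 3.03 to 4.18 for miR170/miR171, 2.72 to 3.82 for miR398, 2.505 to 3.87 for miR160, 1.70 to 2.99 for miR394, 0.93 to 2.26 for miR408 and 1.20 to 2.42 for miR168. With only exact matches, miR170/miR171 was at 7.57, miR167 (0.99, adjusted p = 0.18) and miR396 (1.33, adjusted p = 0.058) no longer passed, miR482 was not tested and miR393 passed (1.71, adjusted p = 0.019). With library sizes from family reads, which lowered the median log2 fold change of the families from 1.30 to 0.29, 9 families were higher and 5 were lower (miR1511, miR159, miR169, miR319 and miR397). With the authors' miRBase annotation, which can take in both arms of a precursor, miR160 was at -0.63 (adjusted p = 0.21), miR170/miR171, miR394 and miR396 no longer passed either, and miR1510 passed (1.26, SE 0.45, adjusted p = 0.022).

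Both arms of a miRNA duplex could be read for 18 families. The opposite arm of miR160, read mainly as GCGTATGAGGAGCCAAGCATA, fell from 803 to 37.3 RPM (log2 fold change -4.30, SE 0.33, adjusted p = 0.0053 over the 18 arms), while the listed arm rose. This sequence holds TGAGG, and the tested sequences with that 5-mer had a mean log2 fold change of -2.22. The leading sequence of the miR170/miR171 opposite arm holds TGAGG too, but that arm was at -0.12 (SE 0.26). The opposite arms of miR159, miR393, miR1510, miR390 and miR319 rose, and the largest of these rises was that of miR159, from 3.93 to 90.9 RPM (4.73, SE 0.42, adjusted p = 0.0053). Their listed arms did not pass the threshold. The opposite arm of miR172 had 5 and 0 counts in mock and 50 and 61 in inoculated roots (4.44, SE 1.65, adjusted p = 0.11). Among the 8 risen families with a measured opposite arm, none of these arms rose past the threshold and that of miR160 fell.

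**Figure D2:**
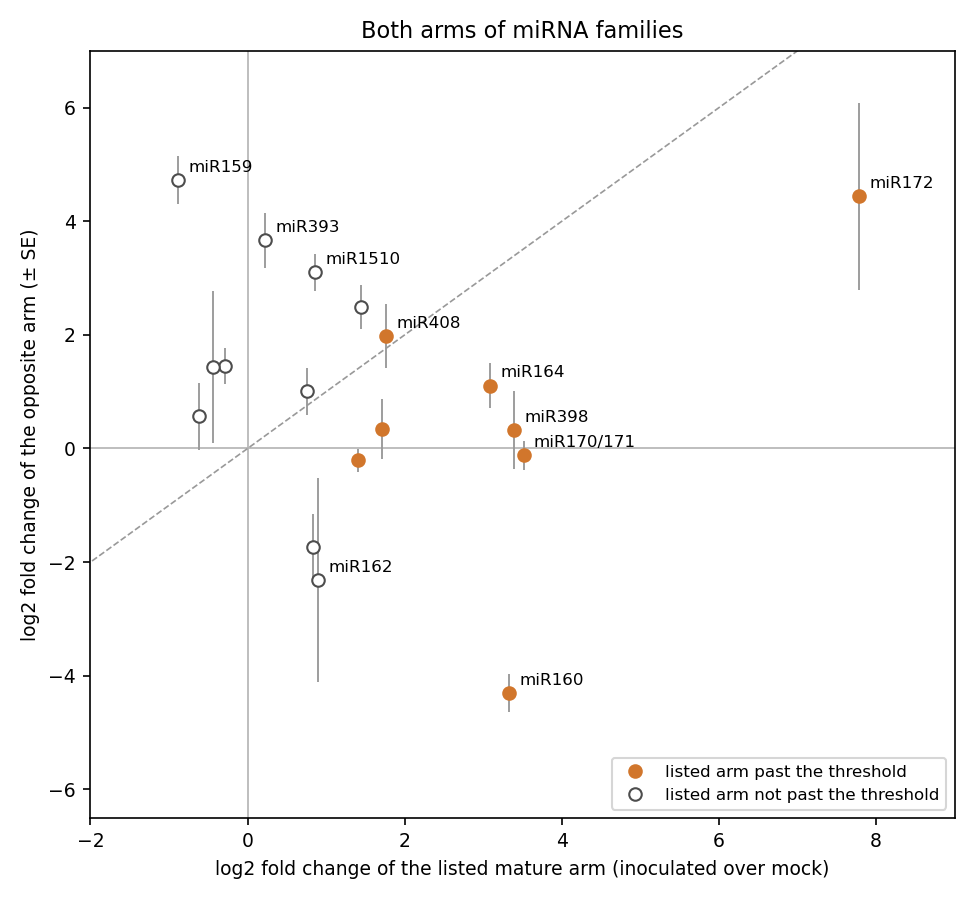
Log2 fold change (inoculated over mock, 2 libraries each) of the opposite arm against that of the listed mature arm, 1 point per family, with bars of ± 1 SE for the opposite arm and a dashed line where both would be equal. Filled points are families whose listed arm passed the threshold. The points for miR160 (3.33 and -4.30) and miR159 (-0.88 and 4.73) lie far from the line. The opposite arms of miR160 and of miR170/miR171 (3.51 and -0.12) hold TGAGG.

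By list, both families of the AP2 and phase change list, miR172 and miR156/miR157, rose (adjusted p = 0.012 by fry, which tests whether a list moves one way, and camera adjusted p = 0.99 with an estimated correlation). Of the 6 auxin signalling families, miR160, miR164 and miR167 rose, and 4 passed when adjusted over the list alone, with miR390 (log2 fold change 1.44) besides (fry adjusted p = 0.044, camera adjusted p = 0.99 with an estimated correlation). Of 13 families reported in legume nodulation, 7 rose, among them miR172, miR170/miR171, miR160 and miR164 (7 adjusted over the list alone, fry adjusted p = 0.044, camera adjusted p = 0.99 with an estimated correlation). The other 6 included miR169 (-0.62, SE 0.48) and miR2111 (0.83, SE 0.92). Of 8 families that target developmental transcription factors, 4 rose, with miR396 and miR170/miR171 beside miR172 and miR156/miR157 (4 adjusted over the list alone, fry adjusted p = 0.089).

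In the copper list, miR398 and miR408 rose and miR397 did not (2 of 3 adjusted over the list alone, fry adjusted p = 0.15). Of 3 measured families that target NB-LRR genes, miR482 rose, and miR1510 and miR2109 did not pass (1 adjusted over the list alone, fry adjusted p = 0.15). Of 2 measured families of the small RNA machinery, Argonaute-targeting miR168 rose and Dicer-targeting miR162 was at 0.90 with SE 0.48 (1 adjusted over the list alone, fry adjusted p = 0.15). None of the 3 measured families of the phosphate and sulphate list rose (0 adjusted over the list alone, fry adjusted p = 0.21). For change in either direction (fry mixed), 5 lists had an adjusted p under 0.05, between 0.0072 and 0.043. Against the other families (camera), no list passed. For the AP2 list, camera gave adjusted p = 0.051 with a preset correlation, and all 8 lists had adjusted p = 0.99 with an estimated correlation. The camera direction of the NB-LRR and the phosphate and sulphate lists was down although their medians were above 0. Leaving out any 1 of the 4 libraries ended each of the 3 fry calls.

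Among single sequences, 31884 of 89736 tested differed between the groups, 20690 higher and 11194 lower in inoculated roots. The groups did not overlap for 69.6% of tested sequences, where chance gives 33.3%. DESeq2 called 21098, leaving out mock A left 17739, and leaving out inoculated B left 17433. By length, 32.2% of 21-nt and 30.5% of 22-nt sequences rose, against 19.7% of 24-nt sequences, and 14.5% of 24-nt sequences fell.

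The 10 sequences with the largest rise by the fixed rule held 8 sequences of the 5′ sequencing adapter, the main miR172 sequence and 1 sequence with no hit to the plant genome, which is not printed here. The adapter sequence TTCTACAGTCCGACGATCGAGA had 0 and 1 counts in mock and 5036 and 7690 in inoculated libraries. The 10 with the largest fall had no count in inoculated roots, 9 were 24 nt long, 9 began with GAA and 2 held TGAGG. Over all tested sequences, the 1347 that began with GAAC had a mean log2 fold change of -3.64, and the 724 that began with GAAT had a mean of -1.88. GAATGCAAGAATAGAAGAAA, first listed at chromosome 3, position 28062450, had 354 and 218 counts in mock libraries. In inoculated roots it was 178-fold lower against the floor (log2 fold change -11.44, and -10.34 without mock A). The exact interval of its ratio, inoculated over mock, reached up to 0.00693, a smaller fall than that against the floor. AATAATGAGGGCAACAAAGATAGT, which holds TGAGG and is listed only at chromosome 4, position 33701590, had 100 and 172 counts in mock. It was 84.7-fold lower against the floor (-10.06), and the exact interval of its ratio reached up to 0.0146. In limma on the authors' scaled values, where a count of 0 is set to 1, the log2 fold changes of these 2 sequences were -6.59 and -5.51.

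Some abundant sequences of the plant genome, chosen after their values were seen, also differed. The 22-nt TTCAGGTCCTTGATCATTCAGC, listed only at chromosome 2, position 19183834, rose from 551 ± 31.0 to 7930 ± 566 RPM (log2 fold change 4.01, SE 0.80, adjusted p = 0.0080). The other strand of its duplex, TGAATGATCAAGGACCTGAATG, listed at position 19183832, had 2771 ± 1388 RPM in mock and 1792 ± 449 RPM in inoculated roots (-0.44, SE 0.67, adjusted p = 0.65). GGAACGTTGTCTGGCTCGAGG, an opposite-arm sequence of miR165/miR166, rose from 195 ± 137 to 1286 ± 189 RPM (2.93, SE 0.69, adjusted p = 0.015, and 3.70 without mock A), while that whole arm, 59 sequences, had 2629 RPM in mock and 4636 RPM in inoculated roots (1.00, SE 0.41, adjusted p = 0.13 over the 18 arms). The ribosomal sequence AAAATGACTCTCGGCAACGGA rose from 294 ± 124 to 2598 ± 1716 RPM (3.31, SE 0.86, adjusted p = 0.021). Its log2 fold change ranged from 2.25 to 3.99 with 1 library left out, and without mock A its adjusted p was 0.12. CCAGGGATCAGCGGATGTTGC, also ribosomal, fell from 506 ± 12.4 to 32.7 ± 0.752 RPM (-3.79, SE 0.56, adjusted p = 0.0052).

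The libraries also differed in the end of the 5′ adapter. Adapter reads that ended in CAGTCCGACGATCGAGA had 18671 and 36858 counts in the inoculated libraries and 10 and 9 in the mock libraries. Those that ended in CAGTCCGACGATCCTCA had 103 and 1252 counts in the mock libraries and 1 and 4 in the inoculated libraries. Each form thus belonged almost wholly to 1 group, and no value within 1 form could be had for both groups. Fold change also went with sequence content. The 5046 tested sequences that held TGAGG had a mean log2 fold change of -2.22 (SE 0.040), the lowest of all 5-mers, and the 1319 that held CTCTC had a mean of 2.53 (SE 0.066), the highest. These SEs are over sequences, which overlap and are not independent, and they do not measure the spread between libraries. Without sequences that held TGAGG, TCTC or GATC or began with GAA or CGG, 20469 of 66339 tested sequences and 11 of 22 tested families were called. All 11 families were higher. They were 10 of the 12 and miR165/miR166, which was at 1.69 (SE 0.61, adjusted p = 0.020), while miR167 and miR398 were no longer tested.

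**Figure D3:**
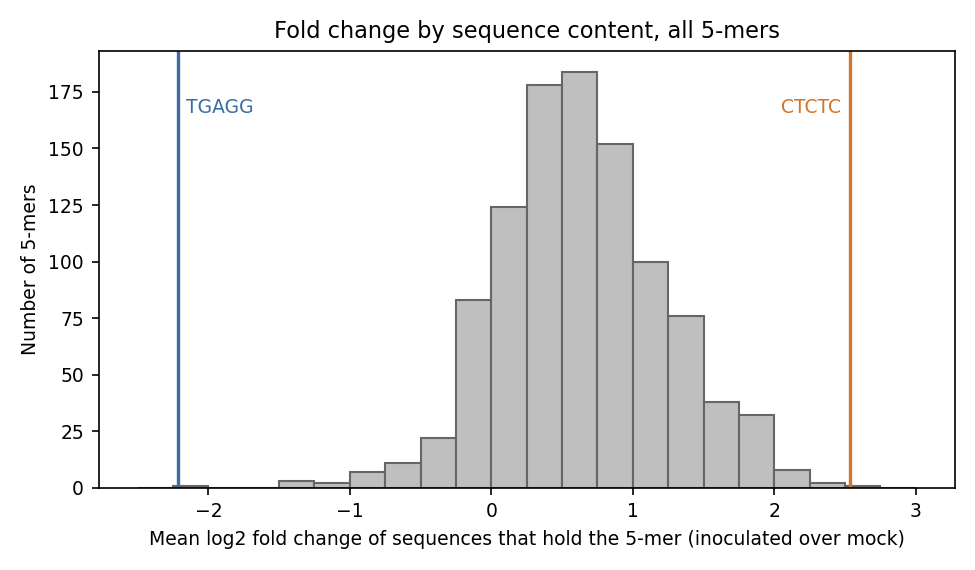
Number of 5-mers by the mean log2 fold change (inoculated over mock) of the tested sequences that hold them, in bins of 0.25. The lines mark the lowest, TGAGG at -2.22, and the highest, CTCTC at 2.53.

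The 24-nt class, typical of siRNAs of repeats, held 46.2 ± 6.89% of counts in mock and 42.2 ± 7.07% in inoculated roots (n = 2 each, exact permutation p = 0.67). The 21-nt class, typical of miRNAs, held 28.9 ± 2.04% and 29.5 ± 2.83% (n = 2 each, exact permutation p = 0.67). The 22-nt class held 14.1 ± 0.388% in mock and 17.5 ± 0.655% in inoculated roots (n = 2 each, exact permutation p = 0.33, the smallest that 2 against 2 libraries can give). As a share of distinct sequences, the 22-nt class held 10.2% in mock and 10.9% in inoculated roots, a difference of 0.685 percentage points in place of 3.47. The 24-nt share was 51.1% and 41.4% in mock A and B and 47.2% and 37.2% in inoculated A and B. The A and B libraries thus differed by more than the groups, and the group difference changed sign when mock A or inoculated B was left out. Leaving out 1 library also unbalances the letters. Within equal letters the difference was -3.87 (A) and -4.13 (B) percentage points, though the labels do not say that equal letters pair libraries.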

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

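The tests on the rank of TGAGG, on M. loti hits and on reads outside the fixed lists were chosen after the result was seen, and those on neighbours, duplex strands and the A libraries were written down after the data were seen but before their own results. Reads of the 5′ adapter made up 0.696 ± 0.0814% of counts in inoculated and 0.0102 ± 0.0086% in mock libraries (SD, n = 2 each), and stand out as reads of no plant RNA with a level above the mock libraries.

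The pattern weighed here is that 31884 sequences differed between the groups. A change of whole duplexes or loci was looked for in 3553 pairs of duplex strands. Their log2 fold changes had r = -0.066 across pairs, which are not independent replicates (95% interval -0.098 to -0.031). The strands of a duplex are reverse complements, and the mean log2 fold change was -2.22 with TGAGG but 1.85 with its reverse complement CCTCA. Such a dependence on sequence can lower r by itself, so the pairs cannot tell whether duplexes or loci changed. The shallower A libraries are argued against by the design, since each group held 1 A and 1 B library. TGAGG sequences also had a mean log2 ratio of -0.195 for mock B over mock A (-0.084 over all sequences), far from -2.22 between the groups. A candidate explanation is a different 5′ adapter end in each group, which may favour inserts that pair with it. TGAGG, the reverse complement of the mock end CCTCA, ranked 1 from the lowest of all 5-mers, and TCTCG, that of the inoculated end CGAGA, ranked 8 from the highest. Whether the adapter acts through the first bases of the insert stays open. By first 4 bases, the mean log2 fold change was -3.64 for GAAC (1347 sequences) and 4.43 for CGGC (412 sequences). For 5-mers at any position the means ran from -2.22 to 2.53. The groups differed in both inoculation and adapter end, so these means cannot tell the 2 apart. Neighbours with the same 5′ end had r = 0.853 and those with the same 3′ end r = 0.771, a difference of 0.082. A response of single strands, duplexes or loci to inoculation stays open too.

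Of 335 sequences with a hit to the M. loti genome and none to the plant genome, 82 were seen only in inoculated libraries and 1 only in mock libraries, and the level above the mock libraries drew attention to them. That is 24.5%, against 5.83% of all other sequences (Fisher's exact test over sequences, two-sided, p = 9.7e-29), and sequences are not independent replicates. These 82 sequences had 530 and 1807 counts in inoculated A and B, and 50 were in both. All 335 together had 309 and 603 RPM in the mock libraries and 479 and 925 RPM in the inoculated libraries. No read held either of the 2 fixed bacterial 16S rRNA sites in any library.

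Annotated reads of several kinds outside the fixed lists were also above their mock level in both inoculated libraries. Predicted ta-siRNAs made up 1.17 ± 0.121% of counts in mock and 1.73 ± 0.118% in inoculated roots (SD, n = 2 each). Sequences predicted as miRNAs by miRDeep-P made up 0.675 ± 0.0948% and 1.30 ± 0.168%, while those predicted by miRDeep2 were lower, at 0.814 ± 0.156% and 0.582 ± 0.0836%. Among 47 families in the authors' miRBase annotation, the log2 fold change was 2.81 (SE 0.56, adjusted p = 2.2e-05) for miR2199, 2.45 (SE 0.95, adjusted p = 0.049) for miR4376 and 2.22 (SE 0.67, adjusted p = 0.0075) for miR4415, which lie outside the fixed list (edgeR quasi-likelihood test). The miR4415 rise leaned on inoculated B, with 114 counts in inoculated A and 1198 in inoculated B. Its level was 25.9 ± 1.36 RPM in mock and 104 ± 86.2 RPM in inoculated roots. The ridge model of sequence predicted 2.64 of 3.34 for the leading read of miR2199, 2.67 of 2.45 for miR4376 and 3.01 of 2.94 for miR4415, and the last 2 reads have no hit to the plant genome.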

How the results depend on the processing

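The tests without adapter, ribosomal, motif or CAG sequences, and camera with a preset correlation, were added after seeing the data. The miR172 rise passed the threshold in all 17 alternatives, with log2 fold changes of 7.03 to 7.97 and 3.83 without the sequence ending in CAG, and adjusted p between 5.6e-54 and 0.011. The count of changed sequences was 21098 with DESeq2, 71988 with no filter on low counts (of 378295 tested), 2185 with at least 50 counts in 2 libraries (of 10907 tested), 20469 without motif sequences, and 17433 to 25684 with 1 library left out, where the lone library of a group is taken to vary like the others. The other alternatives gave 30711 to 43373. Library totals alone moved the median log2 fold change of all sequences by -0.16.

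Families changed numbered 5 to 9 with 1 library left out and 9 to 16 otherwise, apart from the block. With the letters A and B as a replicate block, 43373 sequences and 20 families were called (17 higher, and miR1511, miR159 and miR169 lower), and 1 list in place of 3. The AP2, auxin and nodulation lists had adjusted p = 0.092 with the block, and the developmental transcription factor list passed instead (0.035 against 0.089). Deviations of equal letters from their group means correlated across sequences (r = 0.505), but with 2 letters this does not show that they pair samples. The number of lists called was 0 to 0 with 1 library left out, 0 by camera with a preset and 0 with an estimated correlation. Over 183 values of the 11 other risen families, 153 kept direction and call, 29 lost the call (19 with a library left out) and 1 changed sign, miR160 at -0.63 with the authors' annotation, which adds its opposite arm. Of 603 values of named sequences, 559 kept direction and call and 44 lost the call.

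Over 241 values of the 15 families that were not called, 25 passed the threshold and 14 changed sign. Library sizes from family reads moved the family median by -1.01, which turned the sign of families with smaller rises, miR1510 (-0.040), tasiR-ARF (-0.031), miR165/miR166 (-0.10), miR395 (-0.22), miR2109 (-0.63) and miR393 (-0.59). With the authors' annotation the signs of miR2111 (-0.997) and miR2109 (-0.47) turned. On leaving out a library, miR395 ranged from -0.32 to 1.19, miR2109 from -0.36 (also -0.17) to 0.74, miR393 from -0.18 to 0.74 and miR319 from -0.75 to 0.038 (also 0.035). The cause of the turns other than those from family reads was not tested. The 24-nt difference of -4.0 percentage points ranged from -9.0 to 1.0 with 1 library left out, and within equal letters it was -3.87 (A) and -4.13 (B). In the simulated comparison, with 200 sequences changed and a dispersion of 0.1, 2-fold changes of sequences were unseen. Far fewer sequences changed there than were called in the data, so this does not give the sensitivity of the test in the data.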

Other observations

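The tests on the CAG and CAT sequences, on opposite arms, on scaling (though the fit with library sizes from family reads was set earlier) and on predictions for the 12 families were chosen after the result was seen, and the ridge model of the main miR172 sequence was planned after the data were seen but before its own result. Some miRNA families of other legumes and plants, taken from the authors' miRBase annotation, did not pass the threshold. The miR5281 family had 643 ± 87.8 RPM in mock and 286 ± 36.4 RPM in inoculated roots (log2 fold change -1.03, SE 0.41, adjusted p = 0.053), and miR5213 had 87.4 ± 16.5 and 92.3 ± 32.6 RPM (0.25, SE 0.58, adjusted p = 0.70). Ribosomal repeats gave 9389 tested sequences, of which 2614 rose and 500 fell. Of 1030 tested ta-siRNAs as predicted by the authors' pipeline, 412 rose and 51 fell.

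The rise of miR172 was weighed against the adapter. An adapter end that acts through the first 20 bases is argued against as its whole cause, because the sequences ending in CAG and CAT share these bases. Their log2 fold changes differed by 9.64, beyond the sum of their SEs of 1.37 and 0.52. The comparison does not cover an adapter end that acts through the last base. Sequence preference as the ridge model learned it from other sequences is argued against too. Fitted without the family, the model predicted 10.3% of the log2 fold change of the main sequence (1.29 of 12.50). The residual of this sequence lay at percentile 99.999. That model explained 37.7% of the variance of log2 fold changes in held-out folds and -1.56% with shuffled values. A preference that it does not capture thus stays open. A response of particular miR172 loci to M. loti stays open as a hypothesis. The family without the main sequence was at 3.83 (SE 0.62), but this remainder still held near variants of it.

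The rise of 12 families with none lower is the other pattern. Library scaling is argued against as the whole cause of the rises, since 9 of the 12 stayed higher with library sizes from family reads, but those sizes centre the families and 5 others were then lower, so whether none fell stays open. Sequence preference is a candidate explanation for most of them, because the ridge model predicted a median of 94.3% of the log2 fold change of their 12 leading reads, and at least 50% for 10 of them. The shares were spread widely, from 10.3% for miR172 and 31.7% for miR156/miR157 to 158% for miR482 and 163% for miR394, so single predictions were often far off. The leading reads of the 14 other families had a median prediction of 0.65 against 2.36 for the 12, but the model missed miR1510 (3.98, observed 0.81) and tasiR-ARF (2.84, observed 0.62) by more than its residual SD of 2.10. The opposite arms of 8 risen families had a median log2 fold change of 0.33 but went both ways, from -4.30 (miR160) to 4.44. The miR160 arm holds TGAGG, but so does that of miR170/miR171, which was at -0.12 (SE 0.26). Whether the adapter end or a response of the roots moved these families thus cannot be told apart from these arms.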
